A study of Mus musculus with 5 samples.

How the data were processed

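Droplet-based 3' single-cell RNA sequencing (10x) had been done on 5 mouse libraries, all described as wild type. They were a pool of 20 circumvallate papillae, a pool of 40 foliate papillae, and organoid cultures of clones 1, 3 and 7, which per the labels grew from Lgr5-positive cells of the taste buds. The deposited values are UMI counts per gene and droplet barcode, made by the authors with Cell Ranger on the mouse build mm10. Per the file headers, the filtered matrices of both papilla libraries came from Cell Ranger 6.1.1 and those of the clones from 7.1.0, and the raw matrices of the papillae name version 4. Per the submitters' processing notes, version 6.1.1 was used for all 5. Version 7 counts reads in introns by default and version 6 does not, so the software version, tissue against culture, and papilla against clone cannot be separated by design. Filtered and raw matrices held the same counts for shared barcodes, and the duplicate filtered copies had 0 differing entries.

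Depth was 53699965 UMIs in 6897 called barcodes for circumvallate, 91446089 in 14969 for foliate, and 40830458 in 3656, 49453908 in 4334 and 60666555 in 5040 for clones 1, 3 and 7. Cells were kept with at least 500 genes and at most 20% mitochondrial UMIs, and the top doublet scores were removed at 0.8% per 1000 cells, scored against 2 simulated doublets per cell. This removed 1023, 2194, 642, 505 and 389 barcodes for few genes, 188, 384, 93, 184 and 145 for mitochondrial share, and 315, 1515, 88, 133 and 188 as doublets, in the same order of libraries. A floor of 3 counts corresponded to 0.0219 CPM (UMIs scaled to a library of 1e6) over the summed epithelial cells of the clones and 0.0255 over those of the papillae. Gene identifiers were matched to GENCODE vM21 (GRCm38, the same build as mm10), which held 32235 of the 32285 genes listed.

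Papilla cells were clustered together and clone cells together, without integration, on 2000 variable genes, 30 principal components and 15 neighbours at Leiden resolution 1. The 76 genes of 7 lists were held out of the clustering so that they could be compared between classes. Clusters were named basal-like, keratinizing lingual-like, taste-like, salivary gland-like or non-epithelial from 21 marker lists, by at least 3 markers raised 2-fold and detected in 20% of cells. Basal-like clusters needed 4 of 6 basal markers in 50% of cells and a minimum median depth relative to their libraries. A papilla cluster of 935 cells at 0.452 of the library median passed that minimum. A clone cluster of 636 cells at 0.301 did not. Other clusters with Epcam in at least 20% of cells stayed unnamed. The groups, tests, gene lists and marker lists were chosen before the data were examined, as was the rule for named genes. That rule took the 10 largest changes in each direction past the threshold, with at least 10 CPM in 1 arm and the same sign in every clone, up to 4 members of each list, and Lgr5, Lgr6 and Foxe1. The 16 lists were Wnt targets and receptors, Notch, Hedgehog, BMP, gland, taste and squamous transcription factors (these 7 held out), proliferation, dissociation stress, interferon, regenerative epithelium, secretory endoplasmic reticulum (ER), hypoxia and glycolysis, basement membrane adhesion, mucosal defence and cholesterol synthesis.

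Class shares were given with exact Clopper-Pearson 95% intervals. Circumvallate and foliate papillae had 1 library each, so ratios of CPM over summed epithelial cells were given with exact Poisson intervals and no test. Genes with at least 100 UMIs were counted when the interval lay outside a 2-fold difference, and lists were placed among 10000 random lists of matched expression. Papillae were compared with clones, Lgr5-detected with undetected clone cells, and salivary gland-like with basal-like clone cells on summed UMIs. These tests used edgeR quasi-likelihood fits, TMM scaling, the default expression filter and Benjamini-Hochberg (BH) adjustment at 0.05, with the clone as a block where 2 sums came from each clone. TMM factors were 0.863, 0.868, 1.10, 1.14 and 1.06. In the comparison of papillae with clones, the spread came from the 3 clones and each papilla library was assumed to vary like a clone. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated. For the Lgr5 comparison each cell was thinned to 3000 UMIs, so that detection was taken at equal depth, and Lgr5 itself was left out. A gene with 0 counts in an arm was given as at least a fold at the floor of 3 counts, and one with 1 to 3 counts as a pooled ratio with its counting interval. Intervals and floors cover counting error only. The clones were not stated to come from separate animals, so p-values measure only the spread between these samples.

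Alternatives were DESeq2, no expression filter, no block, all cells, basal-like cells alone, other thinning, other cell filters and clustering, and each library left out in turn. Those added after the data were seen left out 1-library clusters, left out acinar-like clusters, or removed each library's trend on intron length with and without restriction to basal-like cells. The trend was taken over 20 bins of annotated intron length. The tests were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Every gene was given the same dispersion, no differences between clones were simulated, and only well-counted genes were changed. Recovery and false calls in the real data may therefore differ. With edgeR, 37 and 99 of these were recovered for papillae against clones, with 5 false calls. For Lgr5 detection the recovered genes numbered 7 and 57, with 0 false calls, and for salivary gland-like against basal-like cells 34 and 94, with 2. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and igraph 0.11.9. Contrasts with keratinizing or taste-like clone cells were left out at the main setting because clone 3 held 7 keratinizing cells and no clone held taste-like cells. Sequence reads were not used here.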

Results

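Single-cell transcriptomes of the mouse tongue were compared between dissected circumvallate and foliate papillae and clonal organoids. After filtering, 5371 circumvallate cells, 10876 foliate cells, and 2833, 3512 and 4318 cells of clones 1, 3 and 7 remained. Median depth per cell was 8133, 6190, 12760, 12549 and 11722 UMIs, over 2415, 2062, 3903, 3874 and 3608 genes. The comparisons asked which epithelial classes each library held, how the papillae differed from each other, and how the clones differed from tissue. They also asked which genes went with Lgr5 detection inside the clones, and whether Foxe1 and other regulators kept out of the clustering differed between classes.

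Basal-like cells were the largest class in every library, and at the main setting taste-like cells were found in the papillae alone. Basal-like cells made up 70.7% [69.4–71.9] of circumvallate and 74.4% [73.5–75.2] of foliate cells, and 67.3 ± 1.55% (SD, n = 3) of clone cells. Taste-like cells were 3.37% [2.90–3.89] of circumvallate and 2.19% [1.92–2.48] of foliate cells, and 0 of 2833, 3512 and 4318 clone cells. Those zeros allow up to 0.106%, 0.0854% and 0.0695%. The taste-like cells of the papillae fell into 3 clusters. The largest, of 220 cells, carried Shh, the Hedgehog ligand, and the others of 107 and 92 cells carried the type II genes Gnat3 and Plcb2, of taste transduction, and the type III genes Snap25 and Pkd1l3. Classes were named on each clustering separately, and clone clusters with Dcn or Acta2 among their top 10 genes fell into the basal-like class, so its shares are not read as a difference between papillae and clones.

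**Figure D1:**
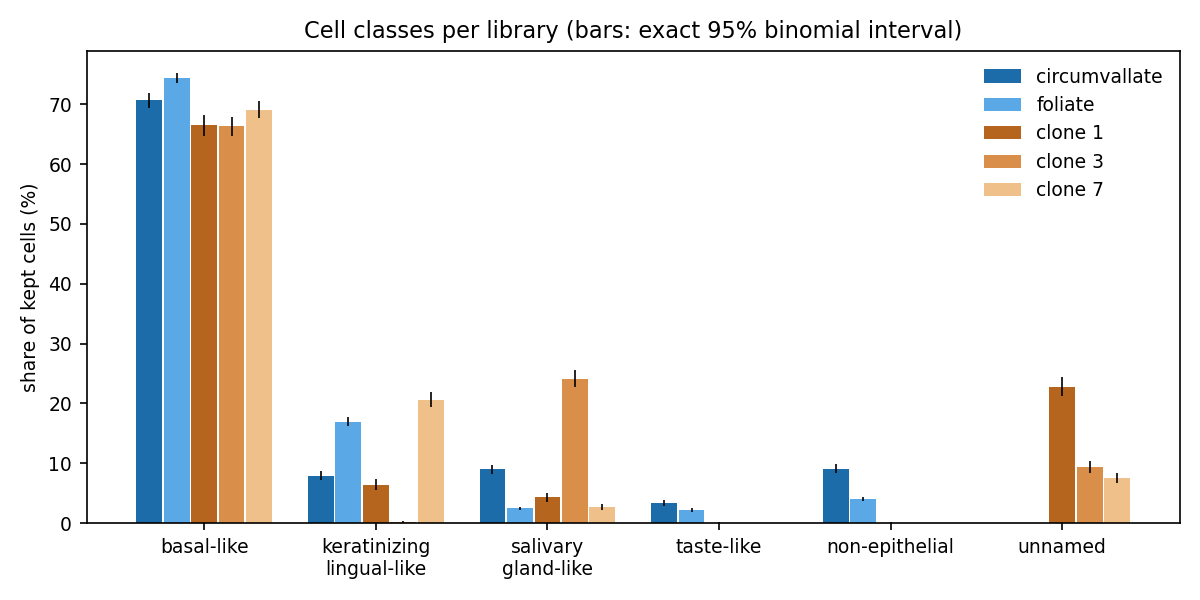
Share of kept cells in each class for the circumvallate and foliate libraries and clones 1, 3 and 7, with exact 95% binomial intervals as bars. Basal-like cells prevail in each library, and taste-like and non-epithelial bars are seen in the papillae alone.

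Keratinizing lingual-like and salivary gland-like shares varied widely between the clones. Keratinizing cells were 6.39%, 0.199% and 20.7% of clones 1, 3 and 7 (9.08 ± 10.5%, SD, n = 3), against 7.89% [7.19–8.65] in circumvallate and 17.0% [16.3–17.7] in foliate papillae. Salivary gland-like cells were 4.31%, 24.1% and 2.69% of the clones, against 8.97% [8.22–9.77] and 2.45% [2.17–2.76] in the papillae. In clone 3 this class was led by Ltf, Krt19, Kcne3 and Agr2, genes of secretory and ductal epithelia. At Leiden resolution 2, clone 3 held 15.3% keratinizing and 6.55% salivary gland-like cells and clone 7 held 10.8% keratinizing cells. With each library clustered on its own the values were 12.7%, 10.4% and 11.3%, so these shares followed the clustering. So did those of the papillae, where keratinizing cells were 11.3% of circumvallate and 10.95% of foliate cells with each library on its own. Cells of unnamed clusters were 22.8%, 9.31% and 7.55% of the clones. These clusters, of 636, 602 and 61 cells, were shallow, with median UMIs at 0.301, 0.102 and 0.0736 of the library medians. That of 636 cells had 5 of 6 basal markers and was left unnamed for its depth, so basal-like shares of the clones depend on that rule. Non-epithelial cells were 9.09% of circumvallate, 4.02% of foliate and 0 of the clone cells.

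Taste markers were also counted cell by cell. Cells with at least 3 of 22 type II and type III markers numbered 107 (1.99%) in circumvallate and 115 (1.06%) in foliate papillae, and 64, 40 and 62 (2.26%, 1.14% and 1.44%) in the clones. Without Itpr3, Ncam1 and Pou2f3, a count chosen after the values were seen, the numbers were 94 (1.75%), 105 (0.965%) and 0, 0 and 0. Gnat3, the taste G protein, had 1617 and 1528 UMIs in the papillae and 0 in each clone, as had Plcb2, Shh and Insm1 in the clones. At a minimum of 1000 genes per cell, 14, 13 and 22 clone cells fell into a taste-like class.

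Circumvallate papillae carried more serous gland and mucosal defence transcripts, and foliate papillae more interferon-induced and keratinizing transcripts. With 1 library per site, these are ratios with counting intervals and no test. Higher in circumvallate were Chia1, an acidic chitinase (42.5-fold [34.0–53.8]), Sval2 (30.3-fold [22.0–43.0]), Clu, the chaperone clusterin (16.7-fold [15.8–17.7]), Amy1, salivary amylase (14.3-fold [13.9–14.6]), and Prb1, a proline-rich salivary protein (14.2-fold). Higher in foliate were Bcat1, a branched-chain aminotransferase (53.9-fold [24.6–147.5]), Serpina9 (28.1-fold [10.8–104.3]), and Akr1c18, a steroid reductase (18.8-fold). The chemokine Cxcl10 was also higher there (8.87-fold [7.14–11.1]), and Cxcl9 had 0 circumvallate UMIs of 126 in foliate. Of 12537 genes with at least 100 UMIs, 276 lay outside 2-fold, 203 higher in circumvallate and 73 in foliate. Within classes the balance turned in basal-like (52 and 73), keratinizing (27 and 146) and salivary gland-like cells (20 and 88), but not in taste-like cells (12 and 6). The classes held different clusters in each library, so these are not ratios between like cells. A keratinizing cluster held 10 circumvallate and 820 foliate cells, and serous and mucous acinar clusters held 70 and 15, and 20 and 45. With clusters drawn almost wholly from 1 library left out, the balance over epithelial cells was 185 and 37. In salivary gland-like cells alone the ratios were 9.94 for Chia1, 8.43 for Sval2, 5.80 for Clu, 3.29 for Amy1 and 3.22 for Prb1, and in basal-like cells alone 2.79 for Clu. With acinar-like clusters left out Sval2 fell under 100 UMIs and Prb1 stood at 30.9-fold.

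Gene groups divided in the same way. Serous acinar markers were higher in circumvallate for 7 of 8 measured (median log2 ratio 2.51, percentile 100), and Lipf, lingual lipase, made up 2.97% of the UMIs of empty circumvallate droplets against 0.316% in foliate. Mucosal defence genes were higher in circumvallate for 4 of 9, among them S100a8 (11.8-fold) and S100a9 (10.8-fold), which also mark leukocytes, and Lcn2 (5.65-fold), an iron-siderophore binder. With ambient UMIs subtracted S100a8 and S100a9 stood at 22.4-fold and 17.5-fold, and in basal-like cells alone at 3.09-fold and 3.93-fold. Taste transcription factors were higher for 2 of 8, Insm1 (3.15-fold) and Foxa2 (2.35-fold), gland transcription factors for 2 of 16, Sox10 (3.39-fold [2.55–4.55]) and Elf5 (2.44-fold [2.12–2.81]), and regenerative epithelium genes for 2 of 9, Clu and Msln (4.35-fold). In salivary gland-like cells alone, the larger class in circumvallate, Sox10 (1.07), Elf5 (1.51), Msln (1.11) and Lcn2 (1.37) did not lie outside 2-fold. Nor did Foxa2 (1.11) and Insm1 (1.84) in taste-like cells alone. Interferon genes were higher in foliate for 5 of 9, led by Isg15 (3.56-fold) and Ifit1 (2.91-fold), and keratinizing markers for 6 of 17, with 1 of 17 higher in circumvallate. No member passed in the Wnt (12 measured), Notch (8), Hedgehog (6), BMP (9), proliferation (20), dissociation stress (15), secretory ER (11), hypoxia (11), basement membrane (8) and cholesterol (11) lists. Their medians were small but not all central among random lists. Wnt (median log2 ratio 0.29), Hedgehog (0.23), BMP (0.10), secretory ER (0.05) and basement membrane (0.05) lay at percentiles from 98.8 to 100. Notch (−0.17), hypoxia (−0.16) and proliferation (−0.21) lay at 0 to 1.49, and stress and cholesterol at 91.3 and 57.3. With clusters drawn almost wholly from 1 library left out, the circumvallate over foliate ratio was 0.866 for Isg15, 1.25 for Ifit1, 0.241 for Bcat1, 0.191 for Serpina9 and 0.309 for Cxcl10, with Bcat1, Serpina9 and Cxcl9 under 100 UMIs, and Foxa2 (2.09) no longer lay outside 2-fold, nor did Elf5 (2.02) with acinar-like clusters left out. Counting all cells raised the count outside 2-fold to 444, of which 376 were higher in circumvallate and 68 in foliate.

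Papillae and clones differed over much of the transcriptome. Among the largest differences were secreted salivary products, with 166311 papilla UMIs and 0 clone UMIs for Dcpp1 (at least 64367-fold) and 659670 against 1 for Lipf. Muc5b, a gel-forming mucin, and Dcpp2 also had 1 clone UMI, and Prb1 and Bpifa2 had 0 (at least 3521-fold and 2351-fold). Lef1, the Wnt effector, and Mt3, a metallothionein, had 0 clone UMIs as well (at least 2844-fold and 2065-fold). Mt4, a metallothionein of stratified epithelia, rose by a log2 of 14.59 (SE 0.83, adjusted p = 0.00235) and Sbpl by 13.99 (SE 0.22, adjusted p = 0.00158). Lower in the papillae were Sncg, gamma-synuclein (log2 −9.09, SE 0.23, adjusted p = 0.00176), Ppp2r2b, a phosphatase subunit (−8.32, SE 0.70, adjusted p = 0.00382), and Esrrg, an orphan nuclear receptor. Prrx1, a mesenchymal homeobox factor, had 3 papilla UMIs and a pooled ratio of clones over papillae of 466 [159–2263]; over all cells, papilla mesenchyme included, it stood at −2.06 and did not pass (adjusted p = 0.103). Of 17250 genes tested with edgeR quasi-likelihood fits and BH adjustment, 8794 passed, 3997 higher and 4797 lower in the papillae. Without clone 1 or clone 7 the count was 4976 or 5000.

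Library software moved with this comparison. Genes with long introns were lower in the papillae, with median log2 changes of 0.30, 0.13, 0.02, −0.16 and −0.80 over 5 equal groups of tested genes from the shortest to the longest introns. With each library's trend on intron length removed, 8331 genes passed (3862 higher and 4469 lower), and 7074 of the 8794 (80.4%) kept their call and direction. Ppp2r2b, with the trend removed, stood at a log2 of −6.35, Sncg at −9.33 and Esrrg at −6.13 against −8.06. Zfpm2, a GATA cofactor with 0 papilla UMIs, did not pass once the trend was removed (adjusted p = 0.0625 against 0.0372), though its fitted log2 moved little (−13.62 to −13.13, no bounds). Lama3, a laminin chain, turned from −1.09 to 0.54 and no longer passed (adjusted p = 0.0908). The calls of Zfpm2, Cyp2j12 and Postn were also lost without 1 or another library (adjusted p up to 0.104, 0.0782 and 0.123).

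**Figure D2:**
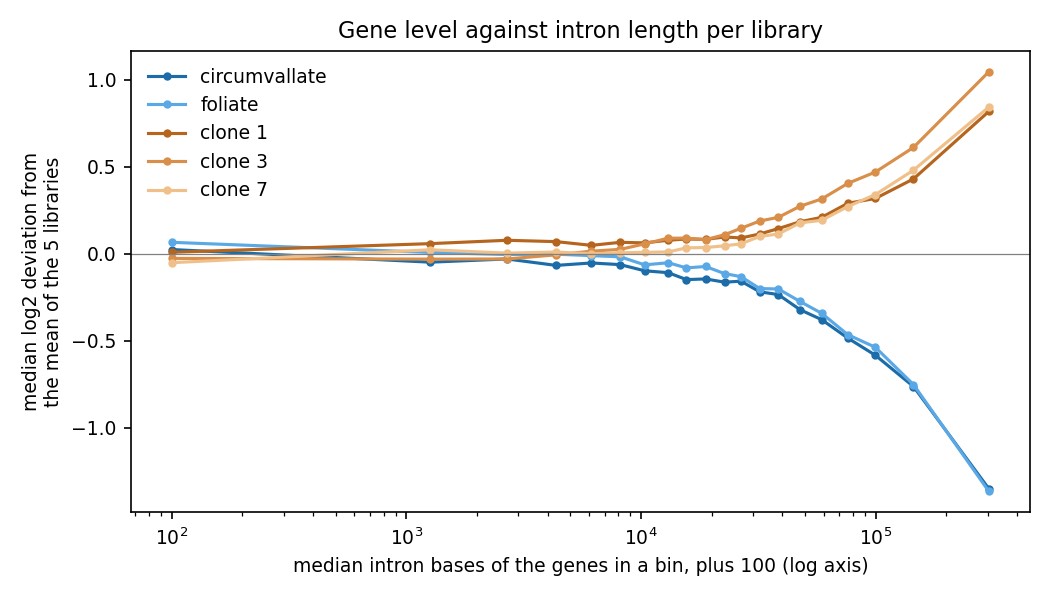
Median log2 deviation of each library from the mean of the 5 libraries (vertical axis) against median intron length per bin in bases (horizontal log axis, 20 bins). Both papilla lines fall and all 3 clone lines rise towards long introns.

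Taste and squamous transcription factors and dissociation stress genes rose in the papillae as groups. Taste transcription factors rose for 7 of 8 measured and fell for 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00498, and adjusted p = 0.618 with an estimated correlation). Among them were Sox2, a factor of taste progenitors (log2 1.39, SE 0.16), Eya1 (3.99), and Prox1, a homeobox factor (7.71, SE 0.91, 6 clone UMIs). With the intron trend removed Eya1 stood at 4.90. In basal-like papilla cells Prox1 stood at 0.241 and 0.202 CPM, and taste-like cells, found in no clone at the main setting, were part of the papilla sums. Squamous transcription factors rose for 6 of 9 and fell for 0, the same adjusted over the list alone, with Klf5 at 2.54, Ovol1 at 3.26 and Klf4 at 1.53 (adjusted p = 0.00419, and adjusted p = 0.618 with an estimated correlation). Immediate early and heat shock genes of the dissociation stress list rose for 14 of 15, the same adjusted over the list alone, with Zfp36 at 4.91, Ier2 at 3.34 and Junb at 2.69 (adjusted p = 1.64e-08, and adjusted p = 0.618 with an estimated correlation). Proliferation genes rose for 9 of 20 and fell for 0, also adjusted over the list alone, with Mki67 at 2.53 and Cenpf at 2.63. Their list test (adjusted p = 0.0499) was lost with the intron trend removed (0.124), without clone 3 (0.116) and without foliate (0.0509), and stood at adjusted p = 0.817 with an estimated correlation.

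Signalling and metabolic lists held genes that moved both ways, and their list tests did not pass. Wnt genes rose for 4 and fell for 2 of 12 (4 and 3 adjusted over the list alone; adjusted p = 0.206), with Ascl2 at 5.79, Tnfrsf19 at 5.32 and Znrf3, a ligase that removes Wnt receptors, at −2.32 (−1.22 with the intron trend removed). Notch genes rose for 4 and fell for 2 of 9 (5 and 2 adjusted over the list alone; adjusted p = 0.216), with the ligands Jag2 at 0.68 and Jag1 at −0.97. Hedgehog genes rose for 5 and fell for 1 of 7 (5 and 1 adjusted over the list alone; adjusted p = 0.114), with Gli1 at 4.45, the receptor Ptch1 at 1.92, Gli3 at −3.56 (−1.81 with the intron trend removed), and Shh with 0 clone UMIs (at least 160.2-fold), which did not pass in basal-like cells alone (adjusted p = 0.056). BMP genes rose for 6 and fell for 2 of 9 (6 and 2 adjusted over the list alone; adjusted p = 0.0609), with the ligand Bmp4 at 9.30 (5 clone UMIs), its target Id3 at 9.16 and Smad6 at −1.92. Gland transcription factors rose for 7 and fell for 3 of 16 (7 and 3 adjusted over the list alone; adjusted p = 0.216), with Creb3l1 at 2.92 and Sox9 at −1.89 (SE 0.18). Creb3l1 stood at −1.05 in basal-like cells alone (adjusted p = 0.168). Hypoxia and glycolysis genes fell for 8 and rose for 1 of 12 (8 and 1 adjusted over the list alone; adjusted p = 0.114), with the carbonic anhydrase Car9 at −6.57, Pgk1 at −2.51, Bnip3 at −3.89 and Hk2 at 1.90.

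Among the remaining lists, mucosal defence genes fell for 3 and rose for 1 of 10 (3 and 1 adjusted over the list alone; adjusted p = 0.359), with Lcn2 at −6.14 (SE 0.64, adjusted p = 0.00541) and the chemokine Ccl20 at −3.04. Regenerative epithelium genes rose for 2 and fell for 3 of 10 (2 and 4 adjusted over the list alone; adjusted p = 0.651), with Anxa3, an annexin, at −2.55. Basement membrane genes rose for 2 and fell for 2 of 8 (2 and 2 adjusted over the list alone; adjusted p = 0.605), with Bcam at 1.63 and Dst, a hemidesmosome component, at 2.46 (4.44 with the intron trend removed). The call of Col7a1 (−0.75), an anchoring collagen, was lost without clone 7 or foliate (adjusted p = 0.0635 and 0.0905). Secretory ER genes rose for 2 and fell for 1 of 11 (2 and 0 adjusted over the list alone; adjusted p = 0.7004), with Dnajb9 at 0.94 and Hspa5 at 0.88, both chaperones. Interferon genes rose for 1 of 10, Rsad2 at 5.58 (0 adjusted over the list alone; list adjusted p = 0.209), whose call was lost without clone 1 (adjusted p = 0.0684). Cholesterol synthesis genes rose for 1 and fell for 2 of 11 (0 adjusted over the list alone; adjusted p = 0.359), and Sc5d and Sqle, enzymes of the pathway, each lost the call without 1 or another library (adjusted p up to 0.0856 and 0.0957). Markers of other cell types rose for 9 of 10 taste type II, 8 of 9 taste type III, 7 of 11 serous, 4 of 5 mucous and 8 of 18 keratinizing genes. Of these lists, 1 type III and 1 keratinizing marker fell. Salivary duct markers rose for 2 and fell for 2 of 5, and endothelial markers fell for 2 of 2.

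Foxe1, a forkhead factor (ENSMUSG00000070990, chromosome 4 at 46343609–46346412 on GRCm38 in GENCODE vM21, a single exon), stood at 107.6 and 71.5 CPM in circumvallate and foliate epithelial cells and at 4.04, 6.20 and 5.87 CPM in the clones. It was higher in the papillae by a log2 of 4.38 (SE 0.23, adjusted p = 0.00217), and by 4.01 (SE 0.24, adjusted p = 0.00331) with the intron trend removed. In the basal-like classes, named separately in papillae and clones, the levels were 130.9 and 82.7 CPM, and 3.98, 7.34 and 5.57 CPM. Between the papillae, with 1 library each, Foxe1 was higher in circumvallate, by 1.45-fold to 1.56-fold (95% counting interval), which did not lie outside 2-fold. The ratio was 1.37 with 1-library clusters left out. In basal-like, taste-like and keratinizing cells alone it was 1.58, 1.06 and 2.32. Lgr5, the R-spondin receptor and stem cell marker (ENSMUSG00000020140, chromosome 10 at 115450311–115587780), and its paralogue Lgr6 (ENSMUSG00000042793, chromosome 1 at 134983301–135105276) hold 127206 and 115125 intron bases. Lgr5 did not pass between papillae and clones (log2 1.14, SE 1.03, adjusted p = 0.398, or 0.166 with the trend removed), but did without clone 3 (2.63, adjusted p = 0.00719). Lgr6 was lower in the papillae by −2.09 (SE 0.32, adjusted p = 0.0115), or −1.33 (adjusted p = 0.0379) with the trend removed. Because of their long introns these levels of Lgr5 and Lgr6 are not read as a difference between tissue and culture.

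**Figure D3:**
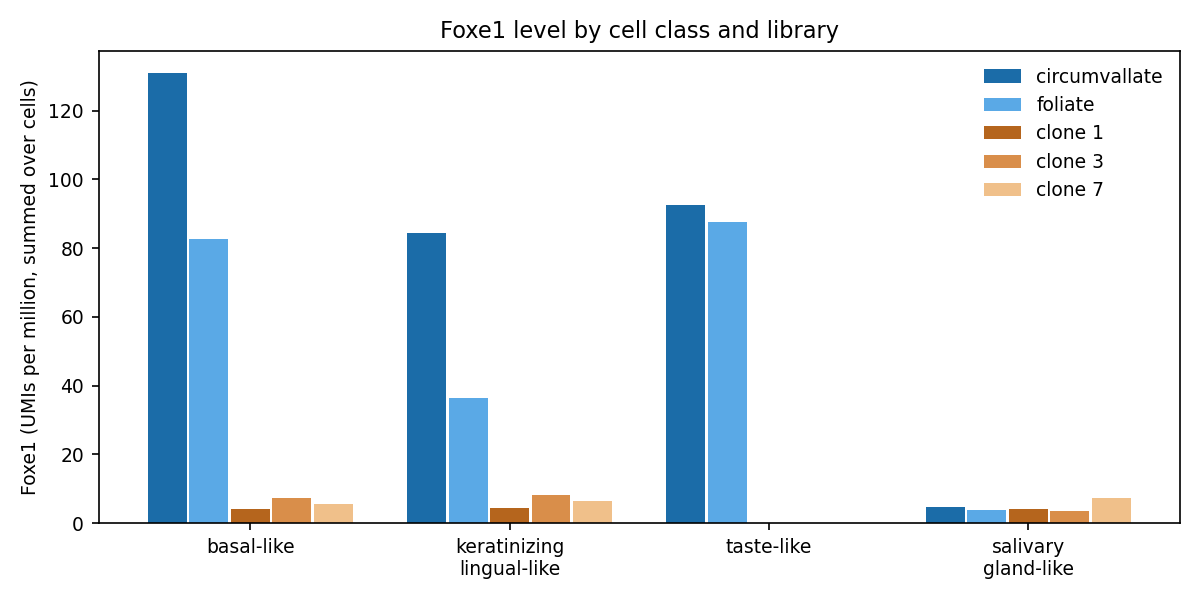
Foxe1 CPM in summed cells of the basal-like, keratinizing lingual-like, taste-like and salivary gland-like classes, with a bar for each of the 5 libraries; classes were named separately in papillae and clones. Papilla bars stand far above clone bars except in the salivary gland-like class, and clones have no taste-like bar.

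Clone cells with a detected Lgr5 transcript carried less Ltf, a salivary duct marker, and less of the chemokines Cxcl1 and Cxcl5 than the other cells of the same clone. With each cell thinned to 3000 UMIs, Lgr5 was detected in 31 of 2120 (1.46%), 181 of 3169 (5.71%) and 30 of 3961 (0.757%) epithelial cells of clones 1, 3 and 7. Ltf, lactoferrin, fell by a log2 of 4.52 (SE 0.37, adjusted p = 2.12e-30, 6 UMIs in detected cells). Gabrp, a GABA receptor subunit, had 0 UMIs in detected cells (at least 8.34-fold lower), and Hp, Krt19, Agr2 and Kcne3 had 1 UMI each (pooled 26.4-fold [4.72–1042], 20.6-fold [3.69–814.9], 20.4-fold [3.65–806.4] and 15.6-fold lower). Of the detected cells 29 of 31, 175 of 181 and 30 of 30 were basal-like, and in basal-like cells alone Ltf stood at −0.61 (adjusted p = 0.975) and Agr2 at −0.86 (adjusted p = 0.999). Cxcl1 there stood at −1.06 (adjusted p = 0.19) and Cxcl5 at −0.75 (adjusted p = 0.0388), and in clone 7 Cxcl5 was nearly equal, at 644 and 670 CPM. Salivary duct markers fell for 3 of 4 (4 adjusted over the list alone) and keratinizing markers for 2 of 9 (8 adjusted over the list alone). Higher in detected cells were Abi3bp (log2 1.60, SE 0.43, adjusted p = 0.0240), Dzip1l (1.36, SE 0.36, adjusted p = 0.0183), the matricellular genes Ccn2 (0.94, SE 0.19, adjusted p = 3.40e-04) and Postn (0.86, adjusted p = 0.00105), the protease Pcsk5 (0.94, SE 0.18, adjusted p = 6.51e-05) and Cd200, a surface ligand (0.95, adjusted p = 0.0177). With the clone as a block, 139 of 11710 genes passed in edgeR, 27 higher and 112 lower. Neither Lgr6 (log2 0.33, SE 0.24, adjusted p = 0.786) nor Foxe1 (0.56, SE 0.76, adjusted p = 0.918) passed. The count fell to 9 in basal-like cells alone (0 higher), to 21 with DESeq2, and to 84, 14 and 73 without clone 1, 3 or 7, and was 0 without the block and 1249 without thinning. Without clone 3, which held most detected cells, no named gene that was higher passed.

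Secretory ER, cholesterol synthesis, proliferation and mucosal defence genes fell as groups with Lgr5 detection in the clones under the preset correlation, and none of them with an estimated one. Secretory ER genes had 0 of 11 members past the threshold (5 lower adjusted over the list alone; adjusted p = 8.77e-06, and adjusted p = 0.375 with an estimated correlation). Cholesterol synthesis genes fell for 2 of 11, Msmo1 (log2 −1.37, adjusted p = 0.00284) and Idi1 (−1.16, adjusted p = 0.0102), and for 4 adjusted over the list alone (list adjusted p = 2.04e-05, and adjusted p = 0.375 with an estimated correlation). Proliferation genes fell for 2 of 20, Cenpf (−1.88) and Ccnb2 (2 UMIs in detected cells, pooled 6.73-fold [1.85–55.7] lower, but 22.2 against 17.0 CPM in clone 7, which held both UMIs), and for 5 adjusted over the list alone (list adjusted p = 6.62e-05, and adjusted p = 0.626 with an estimated correlation). That list did not pass without clone 3 (adjusted p = 0.72). Mucosal defence genes fell for 4 of 7, the same adjusted over the list alone, with the chemokines Cxcl1 (−1.86, adjusted p = 2.73e-08) and Cxcl5 (−1.49, adjusted p = 3.83e-13) and with Lcn2 (−0.89, adjusted p = 1.13e-06). The list's adjusted p was 3.82e-04, and adjusted p = 0.38 with an estimated correlation. In basal-like cells alone Lcn2 stood at −0.19 (adjusted p = 0.947). Regenerative epithelium genes fell for 2 of 10, Anxa1 (−0.72, adjusted p = 3.02e-06) and Anxa3 (−0.82, adjusted p = 0.0076), and for 4 adjusted over the list alone (list adjusted p = 0.06). In basal-like cells alone Anxa1 stood at −0.29 (adjusted p = 0.651) and Anxa3 at −0.69 (adjusted p = 0.19). Gland transcription factors fell for 1 of 11, Etv5 (−1.67, adjusted p = 0.0442), a target of growth factor signalling (2 adjusted over the list alone; list adjusted p = 0.817). No member passed in the Wnt (6 measured), Notch (8), Hedgehog (4), BMP (7), taste factor (4), squamous factor (7), interferon (7), stress (15), hypoxia (12) and basement membrane (8) lists.

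Detection of Lgr5 was weighed against background and depth. In papillae, thinned shares were 4.91% (227 of 4623) in circumvallate and 3.32% (321 of 9679) in foliate epithelial cells. In non-epithelial cells they were 0.388% (1 of 258) [0.00981–2.14] and 1.78% (3 of 169) [0.368–5.10]. The foliate background interval covers the foliate epithelial share, so foliate detection is not set apart from background over all epithelial cells. Unthinned shares were 9.67% and 5.42% in the papillae and 4.71%, 14.3% and 2.30% in the clones. Cells in which Lgr5 was detected after thinning had been shallower before it. Their medians were 11864, 12384 and 10622.5 UMIs in clones 1, 3 and 7, against 15106, 13143.5 and 12293 in undetected cells. Over whole classes of the papillae, Lgr5 was detected in taste-like cells at 11.6% [7.21–17.3] and 13.8% [9.48–19.1], against 5.74% and 3.76% in basal-like cells, while shares in keratinizing cells (0.242% and 0.474%) lay below those of non-epithelial cells and were read as background. The clones held no non-epithelial cells to give such a level. Against the papilla background, the shares of clones 1 and 7 (1.46% and 0.757%) lay within both non-epithelial intervals, and that of clone 3 (5.71%) lay above them. Lgr5 has long introns and the software version differed, so the papilla background cannot decide this for the clones. Within clone 7, Lgr5 was detected in 0 of 889 keratinizing cells [0–0.414], below the 1.01% [0.686–1.45] of basal-like cells. In clone 1 these intervals overlapped, at 0.568% [0.0144–3.12] and 1.58% [1.06–2.26]. Foxe1 was detected in 27.4% [25.9–28.9] of circumvallate and 19.8% of foliate basal-like cells, against 2.71% and 0.592% in non-epithelial cells. In basal-like clone cells it was detected in 1.14%, 1.94% and 1.96%, a range that overlaps the papilla background. That overlap cannot decide whether detection in the clones is background. Over all kept cells Foxe1 stood at 103.8 and 70.3 CPM in the papillae and at 3.96, 6.12 and 5.80 CPM in the clones. Free RNA therefore need not give the same level in both. In salivary gland-like cells of the papillae the Foxe1 shares were 0.860% and 0.787%.

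Salivary gland-like cells of the clones differed from basal-like cells in regulators that had been kept out of the clustering. The class itself followed the clustering. In clone 3 it held 848 cells at the main setting and 230 at Leiden resolution 2, where keratinizing cells rose from 7 to 537. At that resolution 29 of 34 named genes kept their result. Spdef, a secretory lineage factor, rose to 7.04, 9.18 and 6.22 CPM from 0.129, 0.125 and 0.0764 in clones 1, 3 and 7 (adjusted p = 1.52e-04). Zfp750, a member of the squamous list, rose by a log2 of 4.47 (SE 0.25, adjusted p = 6.33e-05), Foxa2 by 4.24 (SE 0.32, adjusted p = 2.26e-04), the Notch target Hey1 by 3.28 (SE 0.25), and Xbp1, a regulator of secretion, by 2.37 (SE 0.15, adjusted p = 1.03e-04). Lower were Lgr6 (−3.07, SE 0.21, adjusted p = 1.63e-04), Lgr5 (−2.96, SE 0.58, adjusted p = 0.0150) and the Notch ligands Jag2 (−2.56, SE 0.20, adjusted p = 2.79e-04) and Dll1 (−2.50). Gland transcription factors rose for 7 and fell for 2 of 14 (8 and 2 adjusted over the list alone), among them Elf5 (3.97, SE 0.73, adjusted p = 0.0113), Etv1 (3.13) and Etv5 (1.84), and Sox9 fell (−0.81, adjusted p = 0.0131). Taste factors rose for 3 of 5 (4 adjusted over the list alone), squamous factors rose for 3 and fell for 1 of 8 (4 and 1), Notch genes rose for 2 and fell for 3 of 8 (4 and 3). Wnt genes rose for 1 and fell for 3 of 11 (1 and 4), BMP genes rose for 1 of 8 (2 up and 2 down), and of the Hedgehog genes 1 of 5 fell, Gli2 (−1.98). Foxe1 did not pass (−0.36, SE 0.35, adjusted p = 0.630). With the clone as a block, 1733 of 14950 genes passed in edgeR, 942 higher and 791 lower. The classes were made by clustering the same cells on genes among those tested, so a high count was bound to follow and is no evidence of its own. Of 59 held-out genes tested, which did not enter the clustering directly, 17 rose and 10 fell (21 and 13 adjusted over the held-out lists alone). The count over all genes was 717 without the block and 3170 without clone 3, and without 1 or another clone Lgr5, Elf5 and Sox9 lost the call (adjusted p up to 0.287, 0.153 and 0.163).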

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

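Of the tests weighed here, those on genes with long introns, on the Foxe1 level, on doublets by pairs of clusters, and on shallow or damaged cells were chosen only after the result was seen.

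The effect of Lgr5 detection differed between papillae and clones for 460 of 12530 genes by a test of the interaction (291 more positive and 169 more negative in the papillae). Lgr5 has long introns, so its detection may not mark the same cells under both software versions. Taste-like cells were also part of the papilla sums alone at the main setting. The interaction therefore cannot be separated from software version and class makeup. The difference between groups was tested for each of these genes. Its log2 value, papillae minus clones, was −3.38 for Abi3bp, 2.04 for Cd200, −1.41 for Bcl11a, 2.68 for Etv5, 0.72 for Anxa1, 3.18 for Cxcl1, 1.65 for Msmo1 and 2.13 for Lgr6. It was 5.90 for Kcne3, 5.48 for Krt19 and 5.77 for Ccl20, which had 1 to 3 UMIs in detected clone cells. For Scgb3a1, Ptprd and Tlcd1, with 0 UMIs in those cells, the fitted 10.85, 11.80 and 9.48 are no bounds. In data outside the main measurement, Lipf made up 2.97% of the UMIs of empty circumvallate droplets and 0.316% of those in foliate.

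The breadth of the difference between papillae and clones was weighed first. The limit set against intron counting as its whole cause was met by the 8331 genes that passed with each library's trend on intron length removed, 7074 of them among the 8794 and in the same direction (1615 were lost, 105 turned and 1152 were gained). That correction removes a trend over length alone, so it cannot decide on effects of intron counting particular to a gene. Calls were not confined to long introns. Of the 3449 tested genes with the shortest introns (median 917 bases), 1018 were called higher and 426 lower in the papillae. The fall of long-intron genes itself, a median log2 of −1.11 between the gene groups with the shortest and longest introns, met what intron counting predicts, but tissue against culture runs along the same line. Other tissues in the papillae could not be weighed by the test set before, since non-epithelial list genes can make up at most 1.35% of genes called higher, so that its value of 0.550% (salivary lists included) was bound to be low; the other part of that test, the count in basal-like cells alone, was met at 8697. Tissue against culture and other effects of the software version stay open.

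The low Foxe1 level in the clones was weighed next. Intron counting was argued against by the log2 change of 4.01 that stayed with the intron trend removed, in a gene of a single exon. By cluster, without use of class names, the highest clone cluster of at least 20 cells reached 7.87 CPM, against 71.5 CPM in foliate epithelial cells. This met the limit set against class makeup but cannot decide it, since some papilla epithelial clusters were also low. Clusters of 830, 599 and 50 papilla cells stood at 10.4, 4.10 and 2.90 CPM, and clones made of such cells would be low too. The smallest fold of either papilla library over any clone in basal-like cells was 11.3, but that class was named separately in papillae and clones and the fold is given little weight. Class makeup, loss in culture, the choice of founder cells, and the software version in some other way stay open.

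Clusters drawn almost wholly from foliate cells were weighed last. Over all 4, the highest percentile of a median doublet score was 88.0, which lies between the limits set before. For the keratinizing cluster of 820 foliate cells led by Krt79 and the interferon cluster of 495 the highest was 69.3, which argues against doublets, while for the pair of small clusters it was 88.0 and doublets stay open. Shallow or damaged cells were argued against by a lowest ratio of median UMIs of 0.833. A state of that library or of its animals stays open, and 1 library cannot test it.

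Other splits of the sums were too few for a share under 0.05. For Lgr5 detection 1 of 10 splits, the real one with 139 genes, reached its own count, and the highest other gave 29. Among the 4 that part every clone 1 did, and the highest other gave 8. For salivary gland-like against basal-like cells 1 of 10 and 1 of 4 splits reached the real 1733 genes, and the highest other gave 0. Those classes were clustered from the same cells, so a high count for the real split was bound to follow.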

How the results depend on the processing

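Alternatives that left out 1-library or acinar-like clusters, or removed the trend on intron length, were chosen after seeing the data. For papillae against clones, none of 80 named genes changed its call under DESeq2, without the filter, or with the papillae as 1 group of 2. The call was lost by 2 genes over all cells, 2 with the intron trend removed (besides Lama3), 9 without circumvallate and 11 without foliate. The count of called genes was 4976, 9826 and 5000 without clone 1, 3 or 7, against 8794. Fewer samples were fitted in each, yet the count rose without clone 3, and the cause was not tested. Creb3l1 reversed to −1.05 in basal-like cells alone and to −0.96 there with the intron trend removed, and Lama3 to 0.54 and 0.62 with the trend removed over all epithelial and over basal-like cells; the cause was not tested. The salivary gland-like contrast gave 1747 genes with DESeq2, 2181 without the filter, 2316 at resolution 2 and 2437 with no doublets removed, against 1733. Without the block 717 genes and 21 held-out genes passed, and in leave-one-out the count ranged from 1214 to 3170.

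The count for Lgr5 detection moved under most alternatives, to 21 with DESeq2, 1249 without thinning, 615 at 5000 UMIs, 9 in basal-like cells alone, 474 with all 5 libraries as blocks, and 14 to 84 in leave-one-out; the cause was not tested. Under edgeR without the replicate block 0 genes passed, with 768 at unadjusted p under 0.05. Of the named genes 21 of 26 lost the call with DESeq2 and 25 of 28 in basal-like cells alone. DESeq2 moved the median log2 change of tested genes from −0.07 to 0.27, over fewer genes. With all 5 libraries Ptprd (1.36), Etv5 (0.18), Cxcl1 (0.066), Ccl20 (1.07) and the Hedgehog list (adjusted p = 0.00756) changed sign, since papilla cells entered.

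Basal-like shares were 68.5% in circumvallate, 73.2% in foliate and 69.1% in the clones (mean) with no doublets removed, and 72.7%, 75.6% and 72.7% at 1000 genes per cell. They were 68.9% and 76.0% in the papillae at resolution 2, 67.4%, 79.5% and 69.1% (clones) with each library clustered on its own, 72.6% in the clones at 10% mitochondrial UMIs, and 79.2% in foliate with 1-library clusters left out. Keratinizing shares in circumvallate were 9.02% at 1000 genes, 10.3% at resolution 2 and 11.3% on its own. In foliate they were 15.4% at resolution 2, 10.95% on its own and 10.8% with 1-library clusters left out, where taste-like and salivary gland-like cells were 2.51% and 2.82%. Taste-like cells were 0.493% of clone cells (mean) at 1000 genes. Circumvallate against foliate gave 444 genes over all cells, and Ifit1 reversed to a ratio of 1.25 with 1-library clusters left out, the clusters in which it was high. No paired analysis was possible because the labels do not say which animals the papillae or clones came from. Whether circumvallate and foliate papillae, or papillae and clones, share animals is therefore not known. Depth limits the Lgr5 comparison, since thinning to 3000 UMIs left 31 and 30 detected cells in clones 1 and 7.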

Other observations

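In the papillae, cells with Lgr5 differed from cells without it in genes whose difference was not seen to the same size in the clones. The genes given were picked, after their values were seen, from the fixed-list genes whose interaction with the clones passed, so that their passing is no separate evidence. In both papilla libraries, thinned to 3000 UMIs, detected cells held more Lgr6 than the others (log2 ratio 2.22 in circumvallate and 2.80 in foliate), more Ptch1, the Hedgehog receptor (2.15 and 3.04), more of the transcription factors Sox2 (1.25 and 1.46), Sox9 (1.19 and 1.44) and Xbp1 (1.44 and 1.69), and more Il33, an alarmin cytokine (2.77 and 3.67). Barx2, a homeobox factor (−2.17 and −1.90), and Dst (−0.76 and −0.99) were lower, and Ccl20 was higher (2.56 and 3.17). Each papilla value rests on 1 library without a test. Only the interaction with the clones was tested in edgeR, and software version and class makeup run along with it. The interaction reached a log2 of 2.86 for Il33 (adjusted p = 1.3e-23), 1.99 for Xbp1 (adjusted p = 1.34e-20), 2.13 for Lgr6, 2.26 for Ptch1 (adjusted p = 6.47e-09), 1.04 for Sox9 (adjusted p = 4.45e-06) and 1.17 for Sox2 (adjusted p = 4.99e-06). Foxe1 stood at 220.3 and 241.9 CPM in detected against 102.8 and 69.8 CPM in undetected papilla cells, but its interaction with the clones did not pass (log2 0.72, adjusted p = 0.737), and it was also higher in the detected cells of each clone, on 1, 4 and 1 UMIs there.

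Lgr5 and Foxe1 varied between papilla clusters, chosen here after their values were seen. A cluster of 1084 cells led by Krt75, Wif1 and Serpine2 had Lgr5 in 43.9% of cells without thinning and Foxe1 at 308 CPM, and a cycling cluster of 128 cells with Wif1, a Wnt inhibitor, had Lgr5 in 71.1% and Foxe1 at 294 CPM. Over whole epithelial sums Foxe1 stood at 107.6 and 71.5 CPM. High Lgr5 was also seen with Foxe1 close to or under those levels, with Lgr5 in 35.9% and Foxe1 at 113 CPM in a cluster of 714 cells with Ntng1 and Il33, and 37.3% and 64.3 CPM in the taste-like cluster with Shh. Type II taste-like cells had Lgr5 in 2.80% and Foxe1 at 187 CPM. Fibroblasts had 1.88% and 5.04 CPM, read as background.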
